A study of Mus musculus with 7 samples.

How the data were processed

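RNA was measured from scrapings of the duodenal lumen of 6-week-old C57BL/6 mice, per the labels: 4 libraries from mice carrying the T337S change in Nlrc4 and 3 from wild-type mice. Each library was assigned to its genotype from its own label. Replicate numbers follow accession order and pair nothing. The labels give no litter, cage, sex, collection day or sequencing batch, and do not say outright that each library came from its own animal. Library titles carry distinct numbers whose meaning is not stated, lower in all Nlrc4-T337S libraries than in any wild-type library. These numbers are odd in the first 4 libraries of the submitters' sample order and even in the last 3. Genotype and sample order cannot be told apart from whatever the numbers stand for. The p-values measure the spread between these libraries. Libraries were made from total RNA with the Illumina TruSeq RNA kit, which does not mark strand, per the labels' protocols.

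Reads were mapped to the mm9 mouse genome with TopHat 2.1.0, and RPKM, reads scaled for gene length and mapped depth, was computed by the authors in Partek 6.16.0606, per the file headers. The submitters' processing notes name TopHat2 2.1. The gene models, and the rule for reads that map to several places, are not given in the sources used here. Whole counts were not recovered from the deposited RPKM values, since gene lengths are not given and the smallest value above 0 was 2.8e-45 RPKM, far below the worth of 1 read; how reads were assigned was not tested. The deposited fraction of mapped reads was read as a percent. Libraries had 45032119 to 95732587 quality-passing reads, of which 84.2% to 97.1% mapped. From these, 1 read per kilobase was worth 0.0124 to 0.0251 RPKM, the coarsest in Nlrc4-T337S replicate 2 which had the fewest mapped reads.

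RPKM is not a count, so no count model was used. Values were tested as log2(RPKM + 0.5) over the 10987 of 22987 listed genes with a mean RPKM of at least 0.5. The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, equal library weights, no covariate and Benjamini-Hochberg adjustment at 0.05; all limma tests were two-sided. Fold changes are on the log2(RPKM + 0.5) scale, Nlrc4-T337S minus wild type, and understate the change of genes near the floor. Nlrc4 and Il18 were tested by two-sided exact permutation of the 35 assignments of 7 libraries to groups of 4 and 3, which cannot go below p = 0.0286.

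The test, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Of 32 fixed gene lists, 30 with at least 3 tested members were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. The sex-linked list served as a check, and the Brunner gland and gastric list had 1 tested member. Camera compares a list with all other genes. The directional p of fry tests whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction; neither compares the list with other genes. Genes were named by 3 rules. Nlrc4 and Il18 were always named. The 10 largest positive and 10 largest negative changes were named among genes that passed, had a mean RPKM of at least 1 in the higher group and no overlap between groups, leaving out predicted genes and receptor segments. From each list, up to 4 members that passed were named, or, where none passed, the 2 with the smallest p, as values only. Genes outside these rules are marked as chosen after their values were seen.

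Alternatives were a pseudocount of 0.1 or 1, no filter or a mean RPKM of at least 2, rescaling every library to the same sum, median-of-ratios scaling, quantile normalization, removal of the pancreatic acinar genes, robust variance estimation, array weights, a threshold of 0.10, camera with an estimated correlation, fry, and leaving out each library. Added after seeing the data were a term for the sign of principal component 2, which follows the submitters' sample order, a term for a crypt and stroma score, and leaving out the 2 Nlrc4-T337S libraries with the lowest score. That score is the mean of the Paneth cell, intestinal stem cell, fibroblast and endothelium, and smooth muscle list scores, so it is built from genes it then adjusts.

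The steps were tested on simulated data with the 10987 genes, 20 simulations and 200 changed genes. Of genes changed 1.5-fold 44.6% were recovered, of those changed 2-fold 92.6% and of those changed 4-fold 99.6%. Of the calls, 5.27% were false, and simulations with no change gave a median of 0 and at most 2 calls. Each gene was drawn independently, without the structure that genes share across the real libraries, so these rates need not hold for the real data. Gene positions came from an mm9 annotation matched by symbol, which covered 90.5% of tested genes; Ciita and Ciart were unmatched. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes of the lists absent from the table, such as Ccl28, Hmgcs1, Igha and Ddx3y, were not analysed here.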

Results

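The series profiled RNA from duodenal scrapings of mice with the T337S change in Nlrc4, an inflammasome protein of the gut epithelium, and of wild-type mice, with 4 and 3 libraries. The comparison asks how gene expression in this tissue differs between the genotypes. Libraries had 45032119 to 95732587 quality-passing reads. Log2 values correlated with a median of 0.986 within genotypes (9 pairs) and 0.981 between them (12 pairs). Principal component 1 held 51.3% and component 2 held 21.4% of the variance. Component 2 was below 0 in the first 4 libraries of the submitters' sample order, 2 of each genotype, and above 0 in the last 3, of which 2 were Nlrc4-T337S and 1 wild type. All libraries had Xist at 11.5 to 17.4 RPKM, Eif2s3y at 0 to 0.00702 and Uty at 0.00248 to 0.00836. This is the marker pattern of female tissue in every library, so the sex markers did not differ in kind between genotypes.

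Nlrc4 itself (chromosome 17, 74825635 to 74858448, mm9) stood at 19.2 ± 0.956 RPKM in Nlrc4-T337S (SD, n = 4) and 19.7 ± 0.940 in wild type (SD, n = 3), a log2 difference of -0.04 (95% interval -0.23 to 0.16; exact permutation p = 0.457). A single amino acid change need not alter RNA level, so this does not check the genotype. Il18 (chromosome 9, 50383378 to 50389942), the cytokine matured by inflammasome caspases, was at 70.8 ± 8.76 RPKM in Nlrc4-T337S and 102 ± 9.93 in wild type, 30.8% lower, without passing: exact permutation p = 0.0571, 0.114 after Benjamini-Hochberg adjustment over the pair, and 0.0876 by limma over all genes. In the inflammasome and pyroptosis list, 1 of 18 tested members passed. Il18bp (chromosome 7, 109163593 to 109166669), the soluble antagonist of interleukin-18, rose from 9.58 ± 1.05 to 18.3 ± 1.14 RPKM (log2 change 0.90, SE 0.10, limma adjusted p = 0.00931 by Benjamini-Hochberg). Adjusted over the list alone, 1 member was higher and 1 lower. The list was not called (camera adjusted p = 0.869).

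Across 10987 tested genes, limma with Benjamini-Hochberg adjustment at 0.05 called 33 genes higher and 65 lower in Nlrc4-T337S, and the groups did not overlap in any of the 98. Over all genes, 2121 (19.3%) had no overlap, where chance gives 5.71% on average over splits. Genes move together, so a single split can lie far from that average. The median log2 change of all tested genes was -0.15, and -0.02 after median-of-ratios scaling, so list medians below are also given relative to it. Of the calls, 33.7% were higher as deposited, 50% after median-of-ratios scaling and 55.6% after quantile normalization. Single libraries decided the counts. Without Nlrc4-T337S replicates 1, 2, 3 and 4 in turn, 17, 74, 25 and 13 genes were higher and 14, 1280, 18 and 14 lower; without wild-type replicates 1, 2 and 3, 11, 9 and 20 were higher and 3, 4 and 65 lower. A crypt and stroma score, averaged from Paneth, stem, fibroblast and smooth muscle genes, was -1.03, 0.18, -0.999 and -0.51 in Nlrc4-T337S replicates 1 to 4 and 0.97, 0.82 and 0.58 in wild type. With that score as a term, limma called 0 genes and 672 had an unadjusted p under 0.05. The score did not overlap between genotypes, so a term for it is hard to separate from genotype. Standard errors grew, from 0.33 to 0.61 for Ubd and from 0.19 to 0.41 for H2-Aa. The 0 calls therefore cannot tell tissue composition from genotype. Without the 2 Nlrc4-T337S libraries of lowest score, 1 gene was higher and 1 lower. All 33 and 65 genes kept their direction there, which their lack of overlap had fixed in advance. All had an unadjusted limma p under 0.05, which choosing them from these same libraries favoured, so neither is independent support. The log2 changes of H2-Aa, Ubd, Reg3b, Dcn and Defa3 went from 2.06, 3.89, -2.42, -1.89 and -3.10 to 2.07, 3.93, -2.41, -1.65 and -2.11. With the score as a term, 30 of the 33 higher and 33 of the 65 lower genes, again chosen from these libraries, had an unadjusted p under 0.05. With the component 2 split, which follows sample order, as a term, 43 genes were higher and 105 lower. In the first 4 and the last 3 libraries of that order, H2-Aa differed by 2.29 and 1.68, Ubd by 3.83 and 4.26, Reg3b by -2.29 and -2.34 and Dcn by -1.97 and -1.52 on the log2 scale. The shared direction of each gene was fixed in advance by its lack of overlap. The last 3 libraries hold 1 wild-type library, so they allow no test of their own.

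The named MHC class II transcripts were higher in every Nlrc4-T337S library than in any wild-type library, a separation their naming rule required. H2-Aa (chromosome 17, 34406276 to 34424772), a class II chain that presents peptides to T cells, rose from 407 ± 109 to 1652 ± 119 RPKM (log2 change 2.06, SE 0.19, limma adjusted p = 0.00679). H2-Ab1, its partner chain, rose from 244 ± 57.6 to 702 ± 63.4, H2-Eb1 from 148 ± 22.5 to 362 ± 37.6, H2-DMb1, which helps load peptide, from 38.6 ± 11.1 to 114 ± 7.78, and Cd74, the invariant chain, from 399 ± 72.8 to 954 ± 122. Ciita, the class II transactivator, rose from 1.27 ± 0.235 to 3.97 ± 0.642 (log2 change 1.33, SE 0.14). In the MHC and antigen processing list 8 of 18 members rose and 0 fell; adjusted over the list alone 13 rose. The list was called upward (median log2 change 0.73, 0.88 relative to all genes; camera adjusted p = 7.98e-32; adjusted p = 0.0456 with an estimated correlation; fry adjusted p = 0.00552). Exons of H2-Aa and H2-Ab1 overlap on opposite strands, and the kit does not mark strand. With the crypt and stroma score as a term, H2-Eb1 changed by 1.57 (SE 0.27), with no call.

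Interferon-gamma-responsive transcripts included the largest rise among named genes. Ubd (chromosome 17, 37330837 to 37333040), a ubiquitin-like modifier, rose from 18.4 ± 10.6 to 261 ± 68.7 RPKM (log2 change 3.89, SE 0.33, limma adjusted p = 0.00638). The immunity-related GTPases Igtp and Irgm2 rose from 26.5 ± 6.95 to 99.8 ± 19.6 and from 9.81 ± 1.26 to 21.1 ± 2.96, and Ifi47 from 13.8 ± 2.35 to 29.2 ± 2.99. In this list 7 of 23 members rose and 0 fell over all genes; adjusted over the list alone 11 rose and 2 fell. The list was called upward (median 0.39, 0.54 relative to all genes; camera adjusted p = 3.71e-18), which was lost at adjusted p = 0.377 with an estimated correlation and at fry adjusted p = 0.0832. The chemokine Cxcl10, of the same list and chosen after its values were seen, was at 0.975 ± 0.101 in Nlrc4-T337S and 3.45 ± 1.86 in wild type (limma adjusted p = 0.0794). With the crypt and stroma score as a term, the change of Ubd was 4.75 (SE 0.61), with no call.

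The type I interferon list had 0 of 21 members called, 2 higher and 1 lower when adjusted over the list alone, and was not called (camera adjusted p = 0.963). Its smallest p-values were those of Usp18, an interferon-induced protease, at 38.6 ± 7.63 and 21.5 ± 0.843 RPKM, and Oas2 at 0.877 ± 0.220 and 1.72 ± 0.201, Nlrc4-T337S first; neither passed (limma adjusted p = 0.0588 and 0.0714). Gzmb, a cytotoxic granule protease, rose from 47.1 ± 1.53 to 75.0 ± 9.61 (log2 change 0.66, SE 0.11, limma adjusted p = 0.0392), the 1 called of 18 tested members of the T cell, intraepithelial lymphocyte and NK cell list, and 1 when adjusted over the list alone. That list was called upward by camera (adjusted p = 8.43e-07, adjusted p = 0.377 with an estimated correlation, fry adjusted p = 0.412). Its median log2 change was only 0.11, or 0.25 relative to all genes. Its library scores overlapped, at -0.15, 0.21, -0.13 and 0.24 in Nlrc4-T337S and -0.18, 0.07 and -0.05 in wild type.

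**Figure D1:**
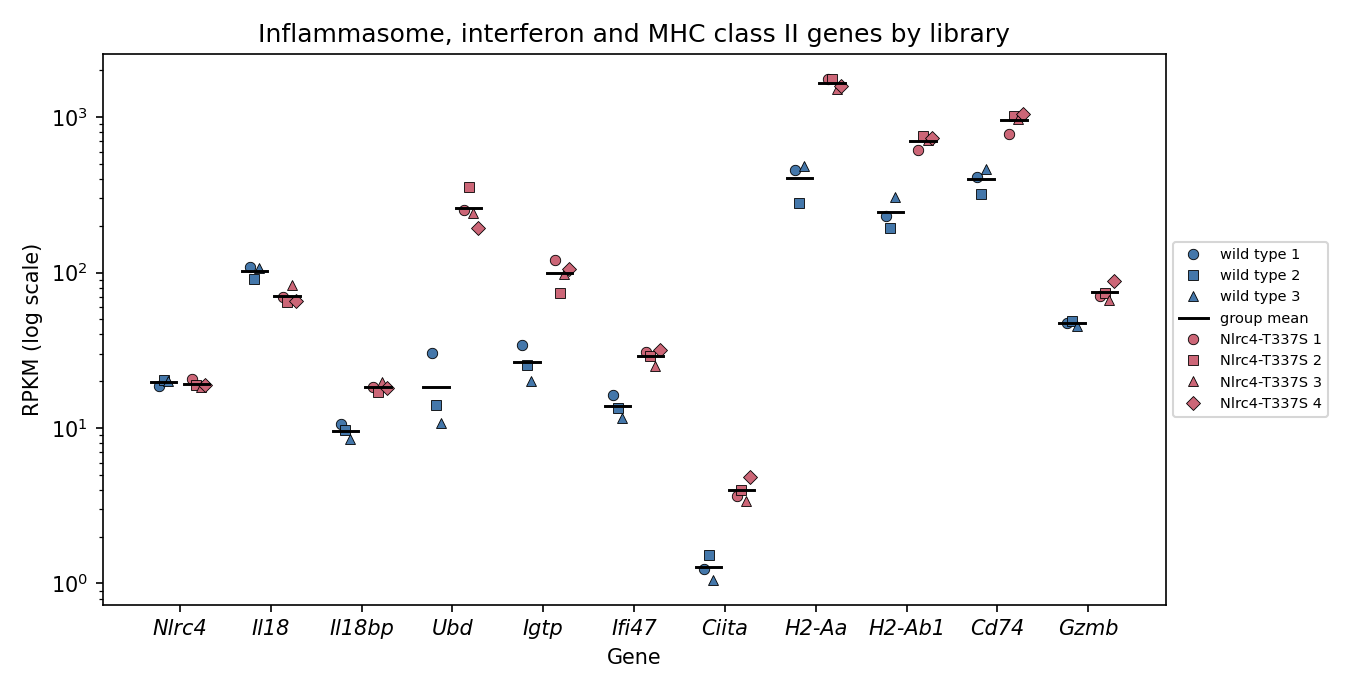
RPKM on a log axis for 11 genes, 1 point per library (blue, wild type; red, Nlrc4-T337S) with group means as bars. H2-Aa lies near 1652 in Nlrc4-T337S and 407 in wild type, while Nlrc4 lies near 19.2 and 19.7.

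Several antimicrobial transcripts were lower in Nlrc4-T337S. Reg3b (chromosome 6, 78320879 to 78323460), a bactericidal lectin, fell from 6339 ± 2242 to 1184 ± 379 RPKM (log2 change -2.42, SE 0.30, limma adjusted p = 0.0138). Nos2, the inducible nitric oxide synthase, fell from 1.26 ± 0.217 to 0.171 ± 0.0811, and Duoxa2, needed for epithelial hydrogen peroxide production, from 1.47 ± 0.243 to 0.375 ± 0.159, its exons overlapping Duoxa1 on the other strand. In the antimicrobial and epithelial defence list 0 of 10 rose and 3 fell; adjusted over the list alone 5 fell. The list was called downward (median -0.83, -0.68 relative to all genes; camera adjusted p = 0.00971; adjusted p = 0.377 with an estimated correlation; fry adjusted p = 0.0154). Reg3 genes are a family of close copies, so their split of reads is uncertain. With the crypt and stroma score as a term, the change of Reg3b was -1.66 (SE 0.56) and that of Nos2 -1.51 (SE 0.28), with no call.

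Several crypt-base transcripts were lower, most of all in Nlrc4-T337S replicates 1 and 3. Defa3 (chromosome 8, 22427088 to 22428056), a Paneth cell defensin, fell from 64.1 ± 15.0 to 9.17 ± 8.10 RPKM (log2 change -3.10, SE 0.56, limma adjusted p = 0.0493), and Mmp7, the protease that matures defensins, from 10.3 ± 1.45 to 2.72 ± 1.71. In the Paneth cell list 0 of 15 rose and 2 fell; adjusted over the list alone 14 fell. It was called downward (median -2.71, -2.56 relative to all genes; camera adjusted p = 4.56e-08; adjusted p = 0.377 with an estimated correlation; fry adjusted p = 0.0732). The defensin copies share reads and are uncertain singly, and with the crypt and stroma score, to which this list contributes, as a term, the change of Defa3 was -0.43 (SE 0.50). With the component 2 split as a term Defa3 and Cdca7 lost their calls (limma adjusted p = 0.0551 and 0.0543), though their log2 changes hardly moved, at -3.08 and -0.97. Of the stem cell list, Cdca7 fell from 3.96 ± 0.333 to 1.79 ± 0.562 (log2 change -0.99; -0.17, SE 0.17, with that score as a term), 1 of 7 members, and 6 fell adjusted over the list alone (camera adjusted p = 0.000309; adjusted p = 0.377 with an estimated correlation). In the proliferation list 0 of 19 passed, all 19 had negative changes and 5 fell adjusted over the list alone (camera adjusted p = 0.00240, adjusted p = 0.604 with an estimated correlation). With the crypt and stroma score as a term this list reversed direction and was called (camera adjusted p = 0.000556). The proliferation score was 0.35 in Nlrc4-T337S replicate 2, level with 0.35, 0.33 and 0.39 in wild type, and -0.71, -0.43 and -0.28 in replicates 1, 3 and 4. The smallest p-values were those of Mcm2, at 0.594 ± 0.372 and 1.61 ± 0.370, and Cdc20, at 1.07 ± 0.671 and 2.36 ± 0.257.

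Some stromal transcripts were lower as well, though the support for the lists as groups was uneven. In the fibroblast and endothelium list 2 of 7 fell, Dcn, a matrix proteoglycan, from 2.54 ± 1.00 to 0.309 ± 0.226 RPKM and Sparc, a matrix glycoprotein, from 2.39 ± 0.9696 to 0.320 ± 0.209 (log2 changes -1.89 and -1.78; limma adjusted p = 0.0207 and 0.0249); adjusted over the list alone 6 fell (camera adjusted p = 0.000359; adjusted p = 0.377 with an estimated correlation; fry adjusted p = 0.0667). In smooth muscle 3 of 6 fell: Tagln from 5.60 ± 1.47 to 1.76 ± 0.410, Myl9 from 3.90 ± 1.61 to 0.567 ± 0.465 and Acta2 from 2.75 ± 1.29 to 0.319 ± 0.330; adjusted over the list alone 3 fell and 1 rose, and the list was not called (camera adjusted p = 0.309). Among the 10 largest falls outside the lists were Fabp4, a lipid-binding protein of endothelium and fat, from 5.11 ± 2.16 to 0.578 ± 0.341, Mmp10 from 6.14 ± 2.93 to 0.817 ± 0.562, Serping1, the C1 inhibitor, from 8.61 ± 3.79 to 1.43 ± 0.912, Sparcl1 from 3.18 ± 1.405 to 0.355 ± 0.237 and Igfbp3 from 3.43 ± 1.30 to 0.525 ± 0.294. In the erythrocyte list 3 of 5 fell, among them Hbb-b1, adult beta-globin, from 35.9 ± 9.68 to 11.7 ± 4.01 and Hba-a1 and Hba-a2, near-identical alpha-globin copies, from 16.3 ± 3.18 to 5.59 ± 1.93 and from 11.9 ± 2.79 to 4.04 ± 1.27; adjusted over the list alone 5 fell (camera adjusted p = 2.56e-05; adjusted p = 0.377 with an estimated correlation). With the crypt and stroma score as a term, the change of Dcn, which contributes to it, was -0.88 (SE 0.39) and that of Hbb-b1 was -1.92 (SE 0.56), with no call.

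**Figure D2:**
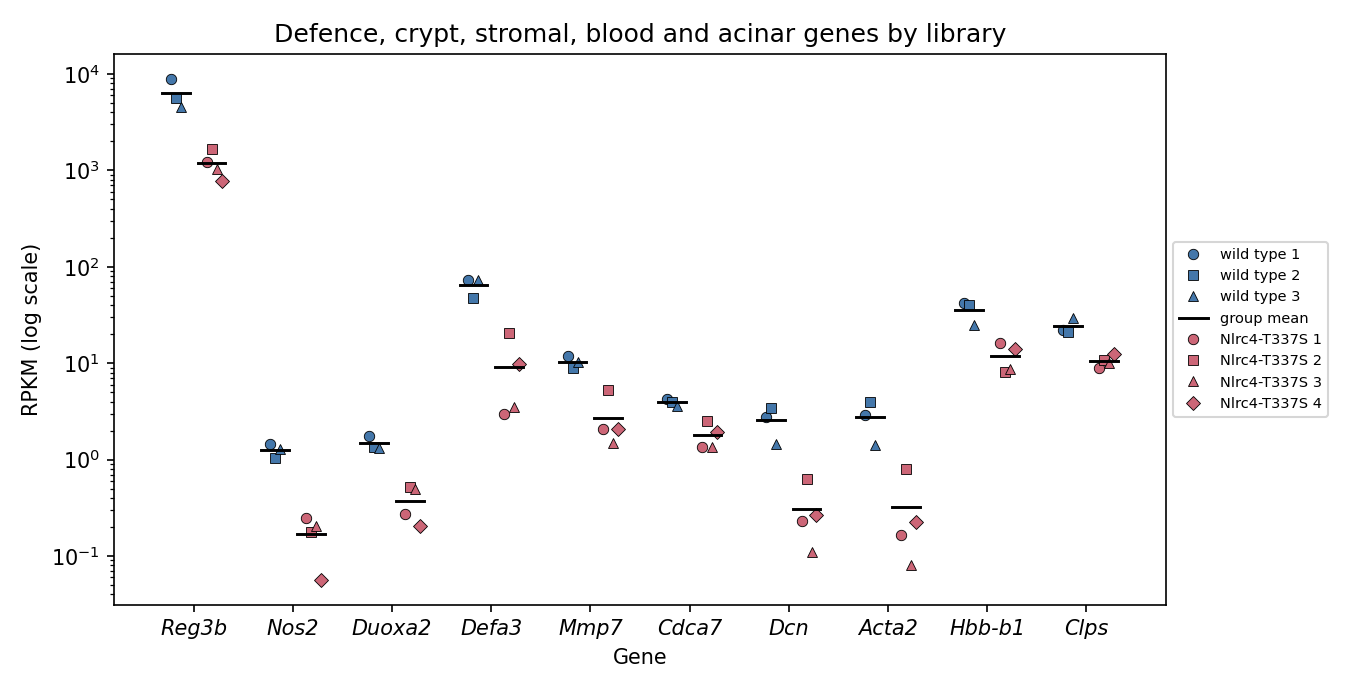
RPKM on a log axis for 10 genes, 1 point per library with group means as bars. Reg3b is near 6339 in wild type and 1184 in Nlrc4-T337S, and Nlrc4-T337S replicate 2 is the highest of its group for Mmp7, at 5.26.

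The macrophage and B cell lists had lower scores in 3 of the 4 Nlrc4-T337S libraries. The mast cell list, with 3 tested members and no call, was lower in all 4 (-0.46, -0.19, -0.27 and -0.09, against -0.01, 0.50 and 0.51 in wild type). Replicates 1, 3 and 4 scored -0.62, -0.85 and -0.19 for the macrophage, dendritic cell and neutrophil list and -0.87, -1.003 and -0.59 for the B cell and plasma cell list, while replicate 2, at 0.34 and 0.63, lay within the wild-type ranges of 0.08 to 0.73 and 0.02 to 1.39. In the macrophage, dendritic cell and neutrophil list 0 of 15 passed, all 15 had negative changes and 8 fell adjusted over the list alone (camera adjusted p = 0.000626, adjusted p = 0.604 with an estimated correlation). With the crypt and stroma score as a term this list reversed direction and was called (camera adjusted p = 0.00124). The B cell list reversed there without a call (0.175). Mrc1, the macrophage mannose receptor, was at 0.443 ± 0.174 and 1.23 ± 0.348 RPKM and Cd209a at 0.702 ± 0.224 and 1.49 ± 0.319. In the B cell and plasma cell list 0 of 10 passed, 5 fell adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.604 with an estimated correlation), with Tnfrsf17 at 0.485 ± 0.277 and 1.71 ± 0.664 and Derl3 at 0.919 ± 0.671 and 2.99 ± 0.852. The pancreatic acinar list, the source of whose transcripts was not tested, had 2 of 7 called. Sycn fell from 1.54 ± 0.451 to 0.132 ± 0.0536 and Clps from 24.1 ± 4.57 to 10.6 ± 1.502. Adjusted over the list alone 3 fell (camera adjusted p = 0.0219, adjusted p = 0.377 with an estimated correlation, fry adjusted p = 0.0278). Hsph1, a heat shock protein, fell from 4.35 ± 0.278 to 2.14 ± 0.489, the 1 called of 14 in the immediate early and heat shock list, also adjusted over the list alone (camera adjusted p = 0.869).

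**Figure D3:**
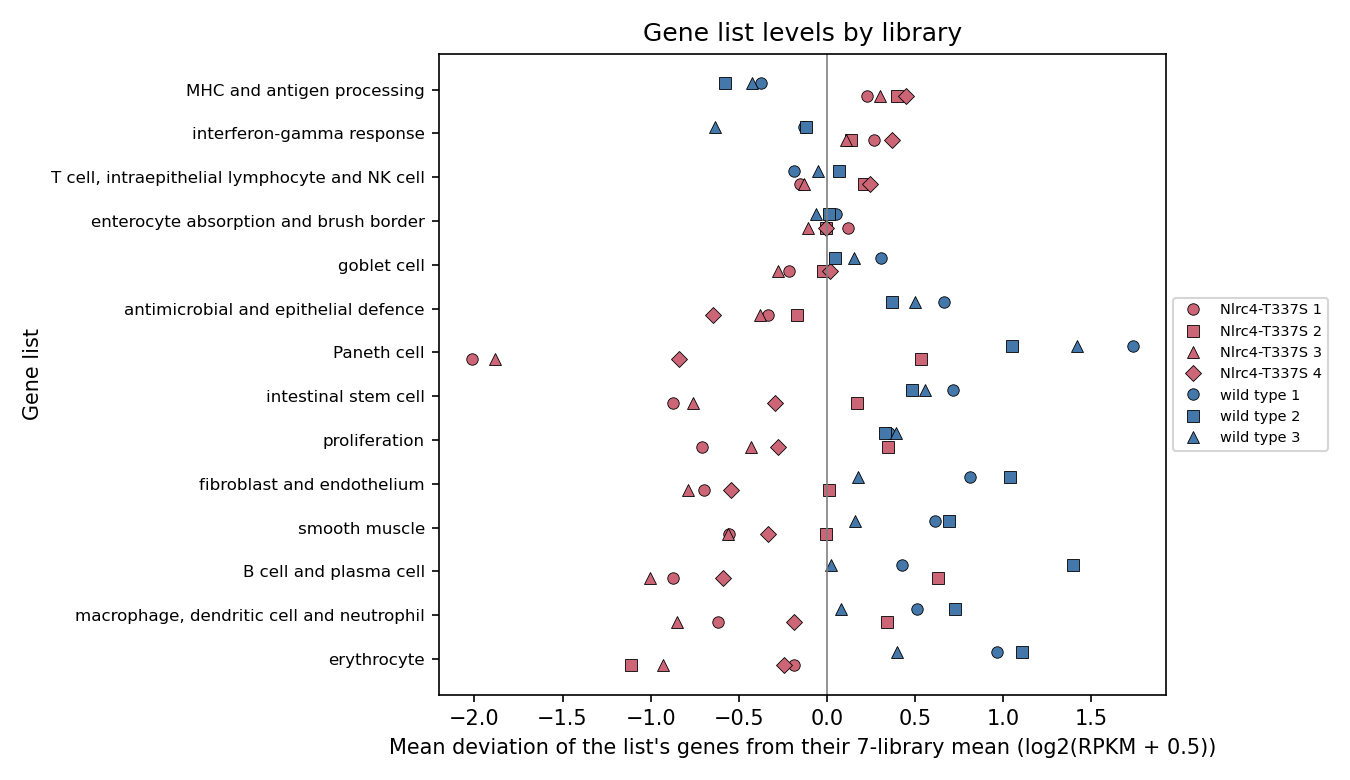
Mean deviation of each list's genes from their mean over 7 libraries, in log2(RPKM + 0.5), 1 point per library. Paneth scores run from -2.01 to 0.54 in Nlrc4-T337S and from 1.05 to 1.73 in wild type, while enterocyte scores stay between -0.11 and 0.12.

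Absorptive enterocyte transcripts had no called member: 0 of 24 over all genes and 0 adjusted over the list alone, with Fabp2, a fatty acid carrier, at 6024 ± 1192 and 4184 ± 1167 RPKM and Cdhr5 at 376 ± 36.8 and 472 ± 39.7. Camera called that list upward (adjusted p = 0.00971; adjusted p = 0.377 with an estimated correlation), with a median of -0.02, or 0.12 relative to all genes, while fry pointed down. The xenobiotic and retinoid list (camera adjusted p = 2.97e-07, adjusted p = 0.377 with an estimated correlation) had median 0.22, or 0.37 relative to all genes, with Cyp2b10 at 437 ± 116 and 265 ± 66.2. The lipid absorption list (camera adjusted p = 0.0115, adjusted p = 0.377 with an estimated correlation) had median 0.00, or 0.15 relative to all genes, and mean -0.03. The cholesterol synthesis list (camera adjusted p = 0.00303, adjusted p = 0.604 with an estimated correlation) had median 0.05, or 0.19 relative to all genes, with Insig1 at 26.3 ± 1.80 and 21.8 ± 0.643. These lists were called upward with 0 members passing over all genes or adjusted over the list alone. The remaining lists were not called, by camera adjusted p: goblet cell 0.132, mast cell 0.0981, eicosanoid synthesis 0.104, inflammatory cytokines and NF-kB targets 0.120, unfolded protein response 0.331, the chromosomal neighbourhood of Nlrc4 0.520, enteroendocrine cell 0.533, circadian clock 0.699, duodenal iron handling 0.701 and tuft cell 0.740. None of their members passed over all genes; adjusted over the list alone, 2 mast cell, 2 eicosanoid, 1 unfolded protein, 1 enteroendocrine, 3 clock and 1 iron gene fell. Camera pointed up where the median was negative for the cytokine, unfolded protein, neighbourhood, iron, inflammasome and heat shock lists. Relative to all genes, only the iron list, at -0.08, stayed negative. Krt7, the 1 tested gene of the Brunner gland list, was at 12.0 ± 2.998 and 16.8 ± 1.61.

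A pair of neighbouring chromosome 17 genes stood among the higher genes. Dynlt1b (6429221 to 6435441), a dynein light chain, rose from 63.6 ± 4.70 to 192 ± 24.3 RPKM (log2 change 1.58, SE 0.12, limma adjusted p = 0.00516). Tmem181b-ps (6439626 to 6489526), chosen after its values were seen, rose from a mean of 4.52 to 10.5 (limma adjusted p = 0.00679). Wdpcp (chromosome 11, 21472238 to 21798992), a planar polarity effector, rose from 3.58 ± 0.163 to 11.2 ± 3.49 (limma adjusted p = 0.0148), and its exons overlap those of Mdh1, chosen after its values were seen, at 1000 ± 86.1 and 838 ± 96.2, on the other strand.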

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

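The tests of explanations and of other splits in this part were chosen after the results they bear on were seen. The spread used for the medians was also changed, from quartiles to an order-statistic 95% interval, after the tests had been run, which altered no verdict. A separate change of rule did alter the verdict of the test on Paneth cells alone, as given below. The intervals of medians run over genes, which move together, so they do not measure the spread between libraries.

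Among 111 sets of Nlrc4-T337S values, 4 had a library far from the other 3, where chance gives about 1 in 20. Wdpcp was at 16.4 RPKM in replicate 1 and 8.86 to 9.98 in the others. Mmp7 was at 5.26 in replicate 2 and 1.48 to 2.08 in the others. Cd209a was at 1.03 in replicate 2 and 0.549 to 0.613 in the others. Pdia4 was at 21.9 in replicate 2 and 16.5 to 17.1 in the others.

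Some Paneth, stem and stromal transcripts were lower in Nlrc4-T337S: 2 of 15 Paneth and 1 of 7 stem members passed, and both lists lost their calls with an estimated correlation (adjusted p = 0.377) and by fry (0.0732 and 0.0598). An effect of the genotype on Paneth cells alone needs stem, fibroblast and smooth muscle genes within 0.25 of all genes. Their median was -0.95 with an interval of -1.64 to -0.47 over 20 members, which argues against such an effect as the whole cause. All 20 belong to the lists that make up the pattern, so this says only that the falls reach past Paneth cells. The test was first left open because the interval stopped short of a bound of -0.5. After that was seen, the rule for this test alone was changed to ask that the interval lie wholly outside 0.25 of all genes. Under the first rule the test stays undecided. Adding the erythrocyte list, tried on seeing the open result, gave -1.12 (-1.35 to -0.57, 25 members). A smaller share of crypt and deeper tissue in the scraping stays open: fibroblast, smooth muscle and erythrocyte genes had a median of -1.22 (-1.64 to -0.57), but 13 of these 18 belong to the lists that make up the pattern, so the value restates it. The erythrocyte list did not follow the other lists, at -1.11 in Nlrc4-T337S replicate 2, the lowest of all libraries, where the fibroblast score was 0.01. A genotype effect on crypt and stroma together also stays open and untested.

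Several MHC and interferon-gamma-responsive transcripts were higher in Nlrc4-T337S: 8 of 18 and 7 of 23 members passed, 6 of the 23 had negative changes, and the interferon-gamma list, unlike the MHC list, lost its call with an estimated correlation (adjusted p = 0.377) and by fry (0.0832). More antigen-presenting leukocytes would raise B cell and myeloid genes, whose median log2 change was -0.88 (interval -1.11 to -0.63, 25 members). Per library, Nlrc4-T337S replicate 2 scored highest of its group, at 0.63 for B cell and 0.34 for macrophage genes, within the wild-type ranges. Its MHC score was 0.40, against -0.58 to -0.37 in wild type. With the crypt and stroma score as a term the macrophage list reversed (camera adjusted p = 0.00124), as did the B cell list (0.175). A larger villus share would raise enterocyte genes by at least 0.5 of the 1.41 seen in the called genes, against a median of 0.12 relative to all genes (interval -0.01 to 0.23, 24 members). Strain DNA around the edited gene on chromosome 17 that acts only on nearby genes would place all 15 called members there. Of these, 6 lie on chromosome 17, 8 lie on other chromosomes and Ciita was unmatched. Position cannot test strain DNA that acts on genes elsewhere. H2-Aa changed by 2.06 (SE 0.19) without and 2.105 (SE 0.41) with the crypt and stroma score as a term, where its adjusted p was 0.490 and its call ended as the error grew. The values argue against more leukocytes, a larger villus share and, as the whole cause, strain DNA acting only on nearby genes. For leukocytes this holds only without the crypt and stroma term. The genotype, litter, cage, microbiota and strain DNA acting at a distance stay open and untested.

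Dynlt1b and Tmem181b-ps, adjacent on chromosome 17, were higher in Nlrc4-T337S. If reads that map to several places are kept, moving them between near-identical copies would leave the sum of Dynlt1a, Dynlt1b, Dynlt1c and Dynlt1f level. The log2 ratio of that sum was 1.30, and ratios between the most extreme libraries ran from 1.02 to 1.66. This argues against a shift of kept reads among these 4 copies. The rule for such reads is not given, so a change in which reads were dropped stays open. The Tmem181 copies were not summed. The 15 other tested genes within 1 Mb had a median absolute log2 change of 0.10 relative to all genes (interval 0.02 to 0.44). A change of copy number or sequence in 1 short segment would give this, but so would regulation of the pair alone. The neighbours therefore cannot tell these apart, and both stay open. Regulation by the genotype was not tested.

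Chance could not be excluded for the number of genes: 2 of 35 splits of the 7 libraries gave as many, the real split with 98 and the highest other with 1371. That split sets Nlrc4-T337S replicate 2 with the wild-type libraries and points to a structure of the samples. For the number of lists, 1 of 35 splits, the real one, gave as many, the smallest share these splits can give; it called 16, the others 3 to 15, so the count of lists hardly sets the real split apart, and the MHC list alone kept its call with an estimated correlation. Component 2 follows the submitters' sample order, so splits that keep 2 of the first 4 and 2 of the last 3 libraries together were also fitted with that order as a term. Of these 18 splits, 1, the real one, gave as many genes (148, highest other 0) and 1 as many lists (16, highest other 14); 18 splits are too few for a share under 0.05.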

How the results depend on the processing

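No paired analysis was possible because replicate numbers are accession order only; the component 2 term stands for a block by sample order. The principal component 2 term, the crypt and stroma term and leaving out the 2 lowest-scoring libraries were chosen after seeing the data. The MHC list kept its direction and call under all its alternatives. Except where stated, the cause was not tested. For Il18, limma gave an unadjusted p of 0.00196. Genes higher and lower numbered 10 and 22 with no filter, 61 and 287 with array weights, and 62 and 250 at a threshold of 0.10; lower genes numbered 28 at a mean RPKM of at least 2 (fewer genes tested) and 105 with the component 2 term; higher genes numbered 54 after median-of-ratios scaling and 74 after quantile normalization. With the crypt and stroma term, whose score did not overlap between genotypes, 0 and 0 passed limma. At unadjusted p under 0.05 there were 672, 485 higher and 187 lower, against 204 and 2237 without it. All 33 and 65 genes of the main fit kept direction, 30 and 33 with unadjusted p under 0.05, though they were chosen from these same libraries. Without the 2 lowest libraries 1 and 1 passed (1223 at unadjusted p under 0.05, fewer samples). Leaving out single libraries gave 9 to 74 higher and 3 to 1280 lower. The median correlation between genotypes was 0.990 with no filter and 0.974 at a mean RPKM of at least 2.

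List adjusted p-values follow. No filter: eicosanoid 0.0345, smooth muscle 0.00146, B cell 0.134. Mean RPKM of at least 2: antimicrobial 0.0661, proliferation 0.109, acinar 0.129. The fibroblast, smooth muscle and mast cell lists had too few members left to be tested there. Median-of-ratios: eicosanoid and mast cell 0.0459. Quantile: eicosanoid 0.0184, goblet 0.00446, lipid 0.595, enterocyte reversed at 0.896. Component 2 term: lipid 0.0550, iron reversed at 0.0270. Crypt and stroma term, whose score is built from Paneth, stem, fibroblast and smooth muscle genes: type I interferon 0.0285, stem 0.767, fibroblast 0.198; reversed were enterocyte 0.198, iron 0.00136, lipid 0.959, xenobiotic 0.416, Paneth 0.767, proliferation 0.000556, B cell 0.175 and macrophage 0.00124. Without the 2 lowest libraries: enterocyte 0.475, lipid and B cell 0.0977, xenobiotic 0.208, smooth muscle 0.0433. With an estimated correlation, the interferon-gamma, antimicrobial, enterocyte, lipid, xenobiotic, Paneth, stem, acinar, fibroblast, T cell and erythrocyte lists had 0.377, and cholesterol, proliferation, B cell and macrophage 0.604. Fry gave interferon-gamma 0.0832, cholesterol 0.882, xenobiotic 0.404, Paneth 0.0732, stem 0.0598, proliferation and macrophage 0.133, fibroblast 0.0667, T cell 0.412, B cell 0.239 and erythrocyte 0.0533, with enterocyte reversed at 0.766 and lipid at 0.898. Leaving out single libraries gave B cell 0.000132 to 0.165, cholesterol 0.000236 to 0.127, eicosanoid 0.0456 to 0.253, enterocyte 0.00231 to 0.109, goblet 0.0268 to 0.4004, cytokines 0.0483 to 0.334, lipid 0.000336 to 0.115, mast cell 0.00421 to 0.220, acinar 0.00334 to 0.146 and smooth muscle 0.0494 to 0.421. Of 36 called named genes, 32 kept their call at a pseudocount of 0.1, 9 with no filter, 34 with the component 2 term, 36 with array weights and 9 without wild-type replicate 1. The depth of Nlrc4-T337S replicate 2 (1 read per kilobase, 0.0251 RPKM) limits genes near the floor such as Sycn and Nos2.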

Other observations

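The values in this part were chosen after the data were seen, and none was tested. The 5 genes S100g, Trpv6, Slc40a1, Cybrd1 and Akp3 fell into separate levels that cross the genotypes and follow the submitters' sample order, in which Nlrc4-T337S replicates 1 and 2 and wild-type replicates 1 and 2 come first. S100g, the vitamin D-dependent calcium carrier, was at 12.6, 11.2, 2395 and 1346 RPKM in Nlrc4-T337S replicates 1 to 4 and at 19.2, 19.8 and 2376 in wild-type replicates 1 to 3. Trpv6, the apical calcium channel, was at 0, 0, 11.7 and 6.53 and at 0.0129, 0.0148 and 11.2 in the same order. Slc40a1, the iron exporter ferroportin, was at 4.28, 2.61, 214 and 200.3 and at 11.8, 12.8 and 208. Cybrd1, a duodenal ferric reductase, was at 0.118, 0.0676, 10.4 and 14.0 and at 0.184, 0.145 and 13.6. Akp3, an intestinal alkaline phosphatase, was at 19.9, 2.73, 950.4 and 721 and at 64.3, 121 and 1413. Tfrc, the transferrin receptor, did not split in this way, at 9.65, 13.8, 9.60 and 6.90 and at 14.4, 12.9 and 10.5.

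Nlrc4-T337S replicate 2 was the highest of its 4 libraries in 41 of 65 lower genes and the lowest in 12 of 33 higher genes, where chance gives 25%.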
